A study of Rattus norvegicus with 36 samples.

How the data were processed

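RNA of rat CG-4 cells, a line of oligodendrocyte progenitor cells, was measured on Affymetrix rat exon arrays. The cells were untreated, carried a transient small interfering RNA (siRNA) against QKI, against hnRNP A1 or without a target, or came from lines with a stable short hairpin RNA (shRNA) against QKI or without a target. These are 6 groups of 3 arrays, which the labels call biological replicates. The series lists 36 samples, since each of the 18 arrays was deposited once at the gene level and once at the exon level. With each gene centred on its mean over the arrays of a table, each array correlated between the tables at 0.958 or higher with itself. With other arrays it correlated at 0.844 or lower.

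The authors deposited log2 values made with RMA, per the submitters' processing notes, which also name Partek. Versions, roles, the genome build and the annotation are not given in the sources used here, nor whether all arrays were brought to 1 distribution. The gene-level table holds 18901 transcript clusters with log2 values from 2.30 to 14.3, and that at the exon level holds 204586 probe sets with log2 values from 2.22 to 14.9. RNA was extracted with Trizol and labelled with a sense-strand kit after removal of ribosomal RNA, per the labels' protocols. The values are log2 intensities, so no read depth applies. The number of arrays limits the precision, and detection calls and scan dates were not used here.

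In the platform annotation 13327 clusters had 1 gene symbol, 620 had several and 4954 had none, and 149521, 962 and 54103 probe sets respectively. Symbols were updated through the RefSeq gene table of assembly GRCr8, used for names only. That matched 13232 clusters by gene number, renamed 39 clusters and 23034 probe sets, and left 13206 symbols at the gene level. No gene is named from a feature with several symbols, and no coordinate is given. Where clusters share a symbol, the one of the highest mean over all arrays was taken.

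All comparisons used limma version 3.58.1 in R version 4.3.3, with data.table version 1.17.8 and statmod version 1.5.0. One mean per group was fitted over all 18 arrays with lmFit and eBayes (12 residual and 3.57 prior degrees of freedom), with two-sided tests and Benjamini-Hochberg adjustment over all clusters. A cluster was called at an adjusted p under 0.05, and ± after a log2 change is limma's moderated standard error, with 3 arrays per group. Exon usage was tested with diffSplice, which sets each probe set against the other probe sets of its gene, with Simes p-values per gene. It took probe sets with 1 symbol and a mean at or above the 25th percentile, in genes with at least 3 of them, which left 115440 probe sets of 10080 genes. A splicing index, the probe set value minus the gene-level value of the same array, was an alternative with a spread for each probe set over 9817 genes. The 27 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a comparison. They cover oligodendrocyte stages, RNA-binding proteins, lipid synthesis, the cell cycle, stress responses, organelles, matrix, signalling and markers of other cell types.

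The groups, tests, lists and alternatives were fixed before the data were examined, and the added alternatives are named as such in the closing section. Named genes are Qki and Hnrnpa1, the 8 called genes per direction with the largest changes in a knockdown comparison and 4 in the others, taken among those at or above the 25th percentile whose groups do not overlap, and up to 4 called members per list. For exon usage the 5 genes of lowest p are named, and listed splicing targets where called. The text gives a part of the genes this rule names. Mbp was followed through all comparisons.

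Each step was tested on simulated data made from the real means and spreads, with 66 or 67 genes changed per fold size. Each feature had 1 spread pooled over all groups and independent noise, so differences between the comparisons are random draws. Real spreads differed between groups, with a median SD of 0.207 for QKI siRNA and 0.153 for non-silencing siRNA, and real arrays shared deviations. The rates are therefore not the power of each real comparison. For QKI siRNA limma recovered 97.0% of genes changed 4-fold, 61.2% at 2-fold and 32.8% at 1.5-fold, with 13 false calls. For QKI shRNA these were 92.4%, 79.1% and 29.9% with 6 false calls, and for hnRNP A1 siRNA 98.5%, 67.2% and 23.9% with 2. In exon usage diffSplice recovered 71.2%, 72.7% and 72.7% at 4-fold in the same order, but with 135, 149 and 141 false calls. In a further simulation without changes, chosen after the results were seen, it made 120, 139 and 144 false calls with the own spread of each probe set and 1, 0 and 0 with 1 spread per gene. The splicing index recovered 62.1%, 74.2% and 71.2% with 3, 1 and 1 false calls. The camera step found the 1 changed list in each of its simulations.

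Replicate numbers come from the labels, which do not say what a number shares. After subtraction of group means, same-numbered arrays of the QKI and non-silencing shRNA lines correlated at 0.25, 0.14 and 0.15, and those of QKI and hnRNP A1 siRNA at 0.53, 0.32 and 0.35. Differently numbered arrays reached at most -0.000688 and 0.167 there. Deviations cancel out within a group, so positive values for the same number push the others down, which are thus not separate evidence. These groups are taken as paired by number. QKI siRNA arrays also correlated with same-numbered QKI shRNA arrays, at 0.34, 0.16 and 0.18, and with those of the non-silencing shRNA line at 0.45, 0.14 and 0.24, and hnRNP A1 siRNA arrays with those of QKI shRNA at 0.34, 0.34 and 0.39. But differently numbered arrays reached 0.268 for QKI siRNA with the non-silencing shRNA line, and 0.485 for untreated with QKI shRNA arrays. The match by number was not tested against chance. Pairs of QKI siRNA or hnRNP A1 siRNA with non-silencing siRNA, and those with untreated cells, did not all exceed 0.1. The replicate number as a block was an alternative. Others were quantile normalization or median centring, filters on dim features, a fold minimum, other variance settings, the compared arrays alone, other controls and each array left out. Correlations of effects were set beside those from 1000 draws in which deviations of arrays from their group means were reassigned, without regard to replicate numbers.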

Results

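Gene expression was measured in CG-4 cells, which stand for oligodendrocyte progenitors, after knockdown of QKI or hnRNP A1. QKI is an RNA-binding protein needed for myelination, and hnRNP A1 is a regulator of splicing. Each of the 6 groups had 3 arrays: untreated cells, non-silencing siRNA, QKI siRNA, hnRNP A1 siRNA, a non-silencing shRNA line and a QKI shRNA line. Values are log2 intensities of 18901 transcript clusters, and 115440 probe sets entered the tests of exon usage. The arrays correlated with one another at 0.937 to 0.991, and 7 of the 18 had their closest partner in another group.

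Transient QKI siRNA was set against non-silencing siRNA to ask what loss of QKI does to these cells. Qki itself lay at 9.99, 10.02 and 9.67 on the 3 knockdown arrays and at 11.47, 11.39 and 11.14 on the 3 controls. Its log2 change was -1.44 ± 0.22, with no overlap of the groups, but it did not pass limma's adjustment over all clusters (adjusted p = 0.179). Mbp, which encodes myelin basic protein, had a log2 change of -2.84 ± 0.70 (adjusted p = 0.31). S100b, a calcium-binding protein of glia, had -1.29 ± 0.27 (adjusted p = 0.29), and Hnrnpa1 -0.33 ± 0.19 (adjusted p = 0.636). Limma called 0 of the 18901 clusters, with 1721 at an unadjusted p under 0.05. Against untreated cells the change of Qki was -1.55 (adjusted p = 0.00862) and 87 clusters were called. The call of Qki was also made without untreated array 3 and QKI shRNA array 3, which share only the estimate of spread here (adjusted p = 0.000586), an alternative chosen after seeing the data. Over all alternatives its adjusted p lay between 0.000586 and 0.472.

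Camera called 9 gene lists after QKI siRNA, although 0 of their members were called over all clusters. Of 25 measured myelin genes 16 were lower, with a median log2 change of -0.32, and 1 higher and 7 lower passed when adjusted over the list alone (camera adjusted p = 0.000143, and adjusted p = 0.48 with an estimated correlation). Of 21 progenitor genes 14 were lower, 3 of them when adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.514 with an estimated correlation). All 8 genes of the small RNA machinery were lower (camera adjusted p = 0.00171, and adjusted p = 0.48 with an estimated correlation), with 0 adjusted over the list alone. Against non-silencing siRNA, the lists of the G2 and M phase, S phase, cholesterol synthesis, stress response, immediate early genes and oxidative phosphorylation were higher. The cell cycle and cholesterol lists had themselves dropped in that control, and group means after QKI siRNA lay below those of untreated cells: 6.81 against 7.60 for G2 and M phase, 6.47 against 6.70 for S phase and 8.66 against 8.74 for cholesterol. In the 6 lists 25 of 28, 27 of 27, 17 of 17, 29 of 33, 25 of 31 and 23 of 33 members were above the control. Their camera adjusted p were 3.29e-06, 0.00171, 0.00124, 0.00179, 0.000331 and 0.0178, and adjusted over the list alone 1 respiratory gene was called higher and 0 in the others. With an estimated correlation no list passed, the smallest adjusted p being 0.48, and fry called 0 (smallest adjusted p = 0.267). The 6 published QKI targets, 1 higher and 3 lower when adjusted over the list alone, were not called (camera adjusted p = 0.0574), nor were the other 17 lists (camera adjusted p from 0.062 to 0.903). The median and the mean differed in sign for splicing regulators, lysosomal, matrix, microglial and Schwann cell genes, none of them called. QKI siRNA array 3 stood apart: its G2 and M phase mean was 5.84 beside 7.51 and 7.07 on the other arrays and 5.64 to 6.17 in the controls, and its S phase mean was 5.74 beside 7.06 and 6.61, with controls at 5.75 to 5.97. Without QKI siRNA array 1 camera called 5 lists, against 9 with it, and did not call G2 and M phase (adjusted p = 0.104), S phase (0.526), cholesterol (0.152), stress response (0.532), immediate early (0.142) or respiratory genes (0.761). The myelin median was -0.15 without that array, and the list still called (adjusted p = 0.0375). The progenitor list was lost without QKI siRNA array 3 (0.097), and the progenitor, stress response and respiratory lists without non-silencing siRNA array 1 (0.07, 0.0815 and 0.249).

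**Figure D1:**
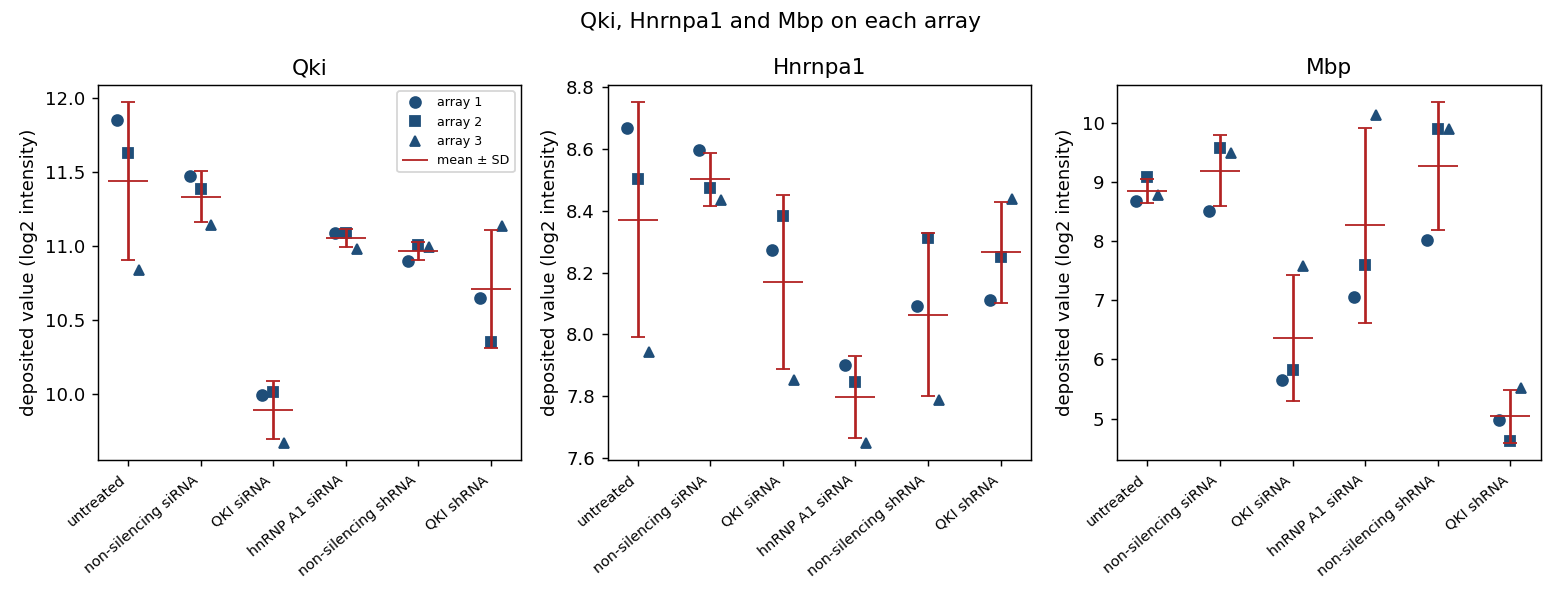
Deposited log2 intensity (vertical axis) of Qki, Hnrnpa1 and Mbp on each of the 18 arrays, by group (horizontal axis), with symbols for array numbers and bars for the mean and SD of 3 arrays; the vertical axes do not start at 0. Qki was lowest after QKI siRNA, at 9.67 to 10.02, while the array labelled QKI shRNA 3 lay at 11.14, above the 3 control-line arrays.

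The stable QKI shRNA line was set against the non-silencing line to ask the same of lasting knockdown. Qki differed by -0.25 ± 0.22 (adjusted p = 0.656), and its values were 10.65, 10.35 and 11.14 in the knockdown line against 10.90, 11.01 and 10.99. The array labelled QKI shRNA 3 thus lay above all 3 controls, so a reduced Qki mRNA is not shown by this line as a group. The control line's mean of 10.97 (SD 0.06) itself lay below the 11.44 (SD 0.53) of untreated cells, with 10.71 (SD 0.40) in the QKI line. Hnrnpa1 differed by 0.20 ± 0.19 (adjusted p = 0.683), and by -0.11 with untreated cells as the control. In the same comparison 1943 clusters passed, 639 higher and 1304 lower, 835 of them by at least 2-fold. With untreated cells as the control 385 passed, 318 of them among the 1943, and with the compared arrays alone 1275, of which 1187 were among them. Of 45 genes named here for this line and called, 21 were also called against untreated cells, 22 kept their direction without a call and 2 reversed. With the compared arrays alone Enpp2, Dusp1, Fdft1 and Mki67, named below, were not called (limma adjusted p = 0.09, 0.156, 0.0673 and 0.0552). The split into higher and lower moved with the scaling: 981 and 1015 after quantile normalization, and 375 and 1086 after median centring.

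Calcr, the calcitonin receptor, had the largest measured rise in the QKI shRNA line, 7.51 ± 0.86 log2 units (adjusted p = 4.5e-05). Il33, an alarmin cytokine, rose by 5.22 ± 0.44, Zdbf2, an imprinted gene in mouse, by 4.13 ± 0.14, and Brinp1, a neural cell-cycle inhibitor, by 4.09 ± 0.49. Most of the Brinp1 difference was a drop in the control line, since it lay at 6.17 in untreated cells, 3.31 in the control line and 7.40 in the QKI line, and it was not called against untreated cells (1.23, adjusted p = 0.311). Slc38a4, an amino acid transporter, Syt4, a synaptotagmin, and Emp3, a membrane protein, rose by 3.88, 3.73 and 3.63. The largest measured drops were those of Hapln1, a link protein of the matrix, with -5.30 ± 0.40, and Pnlip, which encodes pancreatic lipase, with -5.25 ± 0.36. Tril, a modulator of Toll-like receptors, changed by -4.42, Cav1, the main coat protein of caveolae, by -4.28, Pcdh10, a protocadherin, by -4.21 and Gpr37l1, a glial receptor, by -4.04. For each of these genes the 3 arrays of the line lay beyond the 3 controls, and their adjusted p were between 1.02e-10 and 0.000688. The lower group lay near the array medians of 3.77 to 4.18 for several of them, with Hapln1 and Pcdh10 at 3.71 and 3.76 in the QKI line and Calcr, Il33, Zdbf2, Slc38a4 and Emp3 at 3.91, 3.56, 3.63, 3.60 and 4.04 in the control line. For these and Brinp1 the size is at best a lower bound, and the order of sizes is uncertain. Against untreated cells all but Brinp1 were called, with smaller changes: Calcr 4.56, Il33 3.50, Zdbf2 3.88, Slc38a4 3.01, Syt4 2.55 and Emp3 3.34, and Hapln1 -4.53, Pnlip -3.64, Tril -3.17, Cav1 -2.11, Pcdh10 -3.48 and Gpr37l1 -2.48.

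Myelin genes were among those that fell in the QKI shRNA line. Mbp changed by -4.24 ± 0.70 (adjusted p = 0.000919), Enpp2, the secreted enzyme autotaxin, by -3.49 ± 0.77 and Cnp, a myelin phosphodiesterase, by -2.71 ± 0.34. A second, dim cluster of Mbp did not pass, with -0.44 (adjusted p = 0.0789). Of 25 measured myelin genes 6 fell, 0 rose and 19 were not called, and 9 fell when adjusted over the list alone (camera adjusted p = 0.0465, and adjusted p = 0.753 with an estimated correlation). That call was lost without non-silencing shRNA array 2 or 3 or QKI shRNA array 1 or 2 (adjusted p from 0.0788 to 0.12). Of 21 progenitor genes 2 rose and 5 fell, among them Dll3, a Notch ligand, by 2.62 ± 0.59, Sox5, a transcription factor, by -2.02 ± 0.30, and Olig1, a lineage factor, by -1.26 ± 0.28. When adjusted over the list alone 2 rose and 6 fell, and this list was not called as a whole (camera adjusted p = 0.0874). Of 17 astrocyte markers Gfap rose by 2.31 ± 0.57, while Fgfr3, a growth factor receptor, and S100b changed by -3.26 ± 0.52 and -3.68 ± 0.27. Against untreated cells Dll3 and Gfap lay at 0.26 and 0.58, Sox5, Olig1 and Fgfr3 at -1.16, -0.92 and -1.47, and Enpp2 at -2.86, none of them called, while Mbp, Cnp and S100b were. Of the astrocyte markers 2 rose and 3 fell, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.847).

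The lists of cholesterol synthesis, oxidative phosphorylation and lysosomes were lower in the QKI shRNA line, with a part of their members called. Of 17 genes of cholesterol synthesis 8 fell and 0 rose, 11 when adjusted over the list alone, including Tm7sf2, a sterol reductase, by -2.19 ± 0.23, Pmvk, phosphomevalonate kinase, by -1.43 ± 0.21, and Fdft1, squalene synthase, by -1.20 ± 0.24. The list was called (camera adjusted p = 2.15e-05), but not at adjusted p = 0.62 with an estimated correlation. Its mean was 8.98 on non-silencing shRNA array 1, near the 9.11 and 8.92 of QKI shRNA arrays 1 and 2, beside 9.90 and 9.98 on the other controls and 8.11 on QKI shRNA array 3. With each array left out the median lay between -1.39 and -0.67, and camera called the list each time (largest adjusted p = 0.00556). Of 33 genes of oxidative phosphorylation 7 fell and 1 rose, 12 and 1 when adjusted over the list alone, with Ndufv2 of complex I at -1.28 ± 0.15 and Atp5f1c of the ATP synthase at -1.18 ± 0.15 (camera adjusted p = 1.23e-05, and adjusted p = 0.617 with an estimated correlation). Of 33 lysosomal genes 11 fell and 1 rose, 17 and 2 when adjusted over the list alone, among them Lamp2, a membrane protein of the organelle, by -1.49 ± 0.28, Npc2, a cholesterol carrier, by -1.39 ± 0.16, and Ctsd, a protease, by -0.88 ± 0.17 (camera adjusted p = 0.000445, and adjusted p = 0.617 with an estimated correlation). Fry called 7 lists, of the lipid, lysosomal, respiratory, interferon, Schwann cell and published QKI target kinds. With untreated cells as the control Pmvk was at 0.29 instead, none of the other cholesterol, respiratory and lysosomal genes named here was called, and the non-silencing line itself lay above untreated cells in the cholesterol, respiratory and lysosomal lists, as given further on.

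Camera placed the lists of immediate early, interferon and G2 and M phase genes higher in the QKI shRNA line than in the control line, and that of stress response genes lower. The QKI line lay near untreated cells in the latter 2: the G2 and M phase mean was 7.59, with 7.60 in untreated cells and 7.26 in the control line, and the stress response mean 7.38, with 7.42 and 7.81. For immediate early genes it was 5.66, with 5.21 and 5.17, and for interferon genes 4.11, with 3.99 and 3.91. Of 31 immediate early genes 4 rose and 0 fell, 5 when adjusted over the list alone, with Egr1 and Egr3, transcription factors of the growth response, at 3.65 ± 0.99 and 3.27 ± 0.60, and Dusp1, a phosphatase, at 1.68 ± 0.46 (camera adjusted p = 0.00591, and adjusted p = 0.626 with an estimated correlation). Of 34 interferon genes 6 rose and 1 fell, also when adjusted over the list alone: Psmb8, an immunoproteasome subunit, rose by 2.27 ± 0.22 and Bst2, a membrane antiviral protein, by 1.22 ± 0.16, while Ifi27 changed by -1.80 ± 0.27 (camera adjusted p = 0.00873, and adjusted p = 0.617 with an estimated correlation). Of 28 G2 and M phase genes 2 rose, also when adjusted over the list alone, Cenpf by 1.52 ± 0.27 and Mki67 by 1.22 ± 0.34 (camera adjusted p = 0.0463, and adjusted p = 0.874 with an estimated correlation). That call was lost without non-silencing shRNA array 2 or 3 or QKI shRNA array 1 or 2 (adjusted p from 0.115 to 0.277), and that of interferon genes without QKI shRNA array 3 (0.0714). With untreated cells as the control Cenpf was at 0.02, Mki67 at -0.42, Egr1 at 0.95, Dusp1 at 1.62, Ifi27 at -0.31 and Phgdh at -0.45, none of them called. Of 33 stress response genes 3 fell, also when adjusted over the list alone, including Sdf2l1, an endoplasmic reticulum protein, by -3.11 ± 0.29 and Phgdh, an enzyme of serine synthesis, by -1.33 ± 0.30 (camera adjusted p = 0.0112, and adjusted p = 0.753 with an estimated correlation). The list mean was 7.71, 7.61 and 6.82 in the line against 7.76, 7.81 and 7.86, and without QKI shRNA array 3 the median was -0.17 instead of -0.35 and the list was not called (adjusted p = 0.649).

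The other lists were not called in the QKI shRNA line (camera adjusted p from 0.0874 to 0.882). Among splicing regulators 6 of 29 rose and 2 fell, with Nova1 at 1.85 ± 0.48 and Tia1 at -1.75 ± 0.24, and 7 rose when adjusted over the list alone. Of 24 hnRNP genes 0 were called. In Notch and Wnt signalling 2 of 23 rose and 3 fell, with Lef1, a Wnt effector, at 2.31 ± 0.29 and Jag1, a Notch ligand, at -3.46 ± 0.32. Against untreated cells Jag1 was called in the same direction, while Lef1 at 0.73, Nova1 at 0.31 and Tia1 at -0.87 were not (adjusted p = 0.308, 0.913 and 0.079). Matrix genes rose in 5 and fell in 3 of 42 cases, with fibronectin, Fn1, at 1.00 ± 0.12. Called higher and lower were 0 and 1 of 6 published QKI targets, 0 and 4 of 25 fatty acid genes, 0 and 3 of 21 arrest genes, 1 and 1 of 14 heat shock genes, 2 and 3 of 40 cytoskeletal genes, 0 and 1 of 22 ribosomal genes, 2 and 4 of 27 glycolytic genes and 2 and 0 of 8 genes of the small RNA machinery. Of 27 S phase genes 0 were called. Markers of other cell types were called higher and lower in 1 and 2 of 24 neuronal, 1 and 2 of 14 Schwann cell, 0 and 1 of 16 fibroblast and 0 of 17 microglial cases. When adjusted over the list alone, higher and lower were 0 and 3 of the QKI targets, 0 and 6 fatty acid, 6 and 4 matrix, 2 and 5 glycolytic, 2 and 4 Notch and Wnt, 2 and 1 small RNA and 1 and 3 Schwann cell genes. The median and the mean differed in sign for splicing regulators (-0.10 and 0.07), astrocyte markers (0.03 and -0.22), cytoskeletal genes (-0.04 and 0.01), arrest genes (0.09 and -0.06) and Notch and Wnt genes (0.03 and -0.19).

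**Figure D2:**
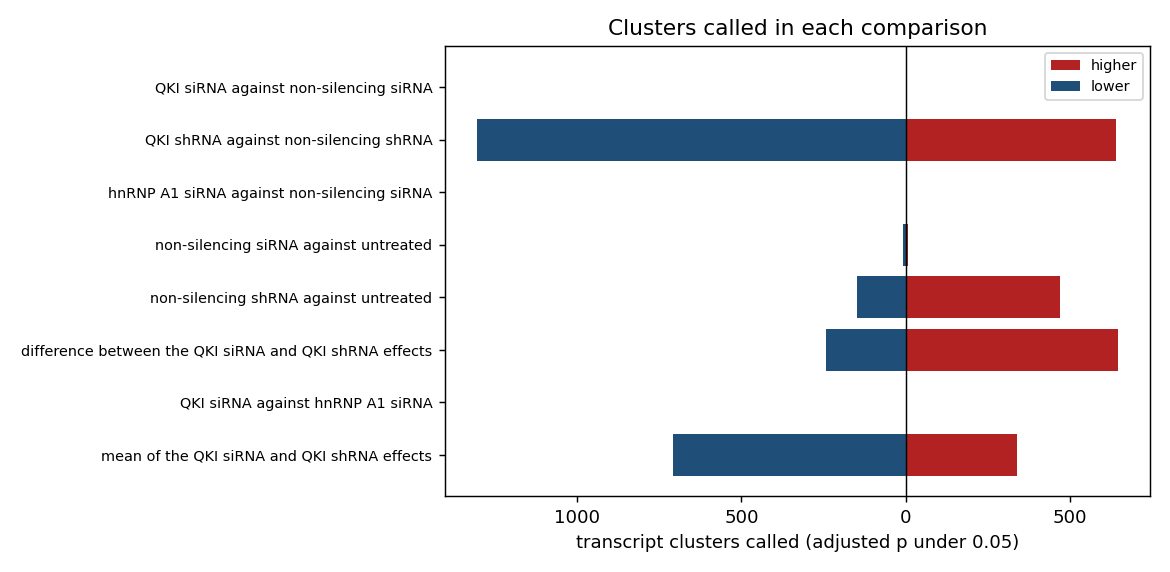
Number of transcript clusters called by limma (horizontal axis) in each comparison (vertical axis), with clusters higher to the right and lower to the left of 0. The QKI shRNA line has 639 higher and 1304 lower, while QKI siRNA has 0.

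Knockdown of hnRNP A1 was set against non-silencing siRNA. Hnrnpa1 lay at 7.90, 7.85 and 7.65 against 8.60, 8.47 and 8.44, a log2 change of -0.70 ± 0.19 without overlap of the groups (adjusted p = 0.393). Qki differed by -0.28 ± 0.22 (adjusted p = 0.902) and Mbp by -0.93 ± 0.70 (adjusted p = 0.895), with Mbp at 7.06, 7.60 and 10.14 on the 3 arrays. Tppp3, a tubulin-binding protein, rose by 1.91 ± 0.21 (adjusted p = 0.00218) and was the 1 cluster called, with 1331 at an unadjusted p under 0.05. Tppp3 was not called with the compared arrays alone (adjusted p = 0.128) or against untreated cells (0.94, adjusted p = 0.0706), where 56 other clusters were. Without hnRNP A1 siRNA array 3 limma called 26 clusters. Of 33 respiratory genes 31 were higher, 8 of them when adjusted over the list alone (camera adjusted p = 1.2e-10, and adjusted p = 0.594 with an estimated correlation). Camera also placed higher the lists of cholesterol synthesis (adjusted p = 6.32e-06), stress response (0.000197), G2 and M phase (0.00157), immediate early (0.00772) and glycolytic genes (0.0494), and lower those of myelin and progenitor genes (0.0484 each). Of these 7 lists only the immediate early genes held members called when adjusted over the list alone, 2 higher, and each had an adjusted p of 0.602 or 0.633 with an estimated correlation. The cholesterol and G2 and M phase lists had dropped in non-silencing siRNA, and against untreated cells their group means were 8.75 beside 8.74 and 6.56 beside 7.60. The G2 and M phase mean was 7.22, 6.56 and 5.89, so array 3 lay inside the control range of 5.64 to 6.17, and the list was not called without hnRNP A1 siRNA array 1 (adjusted p = 0.439) or non-silencing siRNA array 1 (0.15). The calls of progenitor, myelin, immediate early and glycolytic genes were each lost without 2 or more single arrays, among them hnRNP A1 siRNA arrays 1, 2 and 3 and the 3 controls (adjusted p from 0.0621 to 0.359). Fry called 0 lists (smallest adjusted p = 0.134), and the other 19 were not called by camera (adjusted p from 0.0806 to 0.938).

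Non-silencing siRNA was set against untreated cells to see how this control differs from them. Its G2 and M phase mean was 5.99, beside 6.81 after QKI siRNA, 6.56 after hnRNP A1 siRNA and 7.60 in untreated cells. For cholesterol genes these were 8.22, 8.66, 8.75 and 8.74, so the full shifts were not shared by all transfected groups. An effect of this siRNA alone cannot be told apart from one of transfection. Genes of the G2 and M phase were lower in all 28 of 28 cases, with a median of -1.69, and Cenpf and Mki67 changed by -2.05 ± 0.27 and -1.97 ± 0.34 (adjusted p = 0.00693 and 0.0478). Adjusted over the list alone 26 fell (camera adjusted p = 1.84e-31, and adjusted p = 0.192 with an estimated correlation). All 27 S phase genes were lower with a median of -0.73, and 0 were called (camera adjusted p = 6.26e-11, and adjusted p = 0.47 with an estimated correlation). The S phase mean was 7.57 on untreated array 3 beside 6.29 and 6.25, and without that array the median was -0.33 and the list still called (adjusted p = 0.000491), while the G2 and M phase median was -1.35. Ddit3, a transcription factor of the stress response, rose by 1.78 ± 0.27, Retsat, a retinol saturase, by 1.70 ± 0.29, while Papss2, a sulphate donor synthase, and Gria3, a glutamate receptor subunit, changed by -1.74 ± 0.28 and -1.47 ± 0.20. Of 33 stress response genes 1 rose, 10 when adjusted over the list alone with 1 lower (camera adjusted p = 0.000328, and adjusted p = 0.59 with an estimated correlation). Camera placed lower the cytoskeletal list (32 of 40 genes lower, adjusted p = 6.88e-10), with 0 genes called over all clusters, 5 lower when adjusted over the list alone and an adjusted p = 0.0986 with an estimated correlation, and the cholesterol list (16 of 17 lower, 3.82e-07, and adjusted p = 0.437 with an estimated correlation). Smaller shifts down by camera were those of the lists of hnRNP (0.00169), fatty acid (0.0125), Notch and Wnt (0.0216), splicing regulator (0.0296) and progenitor genes (0.0441), at adjusted p from 0.192 to 0.59 with an estimated correlation. Adjusted over the list alone, 1 fatty acid gene was higher and 5 lower, 1 and 3 of Notch and Wnt, and 2 splicing regulators lower. The progenitor call was lost without untreated array 1 or 2 or non-silencing siRNA array 3 (adjusted p from 0.203 to 0.505), that of Notch and Wnt without untreated array 1 or 2 (0.161 and 0.0825), and those of splicing regulators and fatty acid genes without non-silencing siRNA array 1 (0.189 and 0.0551). Fry called 0 lists (smallest adjusted p = 0.0564), and the other 17 were not called by camera (adjusted p from 0.114 to 0.977). Mbp lay at 0.34 ± 0.70 (adjusted p = 0.869). Limma called 15 clusters, 6 higher and 9 lower, and 1953 lay at an unadjusted p under 0.05. The split was 8 and 17 after quantile normalization and 1 and 3 after centring, which moved the median of all clusters from 0.08 to -0.04. The count was 51 without untreated array 3, 2 and 3 without untreated arrays 1 and 2, and 8, 5 and 3 without non-silencing siRNA arrays 1, 2 and 3.

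**Figure D3:**
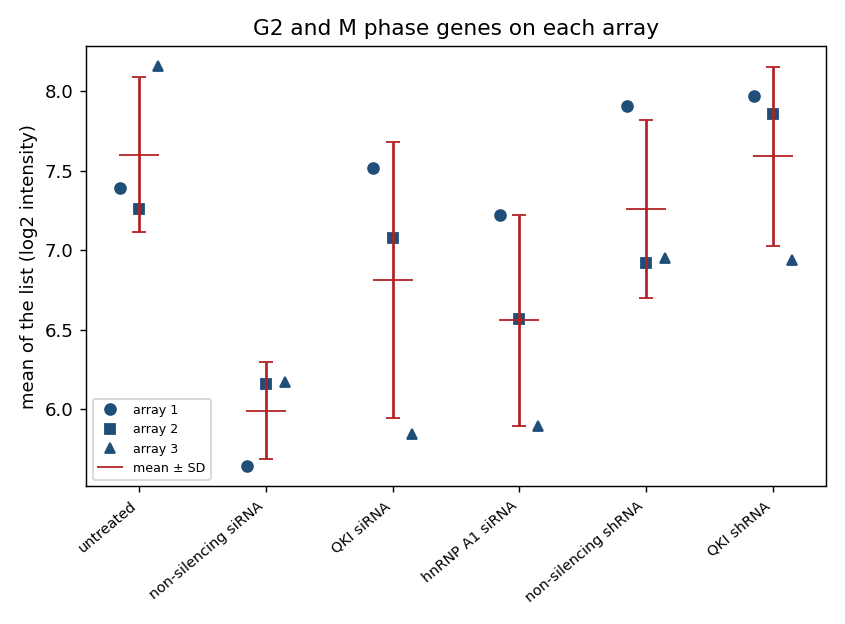
Mean log2 intensity of 28 G2 and M phase genes (vertical axis, not starting at 0) on each array by group (horizontal axis), with symbols for array numbers and bars for the mean and SD of 3 arrays. Non-silencing siRNA lies at 5.64 to 6.17, below all untreated arrays, and within QKI siRNA the arrays span 5.84 to 7.51.

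The non-silencing shRNA line was set against untreated cells for the same reason. Fxyd1, a regulator of the sodium pump, rose by 2.24 ± 0.27 and Prph, a neuronal intermediate filament, by 1.86 ± 0.24, as did Mat2a, which makes S-adenosylmethionine, by 2.28 ± 0.58, and Cav1 by 2.16 ± 0.45. Brinp1 changed by -2.86 ± 0.49, Ndn, an imprinted gene in mouse, by -2.42 ± 0.26, Sparcl1, a matrix glycoprotein, by -2.39 ± 0.60 and Dll3 by -2.36 ± 0.59. Of 17 cholesterol genes 4 rose, 8 when adjusted over the list alone, with Tm7sf2 and Pmvk at 1.80 ± 0.23 and 1.72 ± 0.21 (camera adjusted p = 1.7e-06, and adjusted p = 0.561 with an estimated correlation). Of 33 respiratory genes 8 rose, 20 when adjusted over the list alone, with Ndufv2 and Uqcrfs1 of complex III at 1.11 ± 0.15 and 1.11 ± 0.20 (camera adjusted p = 5.53e-10, and adjusted p = 0.346 with an estimated correlation). Of 33 lysosomal genes 5 rose, 8 when adjusted over the list alone, with Gabarap and Npc2 at 1.14 and 1.05 (camera adjusted p = 0.00267, and adjusted p = 0.561 with an estimated correlation). Of 28 G2 and M phase genes 2 fell, 3 when adjusted over the list alone, Cenpf with -1.51 and Mki67 with -1.64 (camera adjusted p = 0.00061, and adjusted p = 0.597 with an estimated correlation). Of 25 myelin genes 1 rose and 4 fell, among them Mog, Enpp6 and Nfasc with -1.13, -1.39 and -1.87 (camera adjusted p = 0.114), or 2 and 5 when adjusted over the list alone, with a median of 0.07 and a mean of -0.12. Mag, a published QKI target, had -1.81, and Mbp 0.42 ± 0.70 (adjusted p = 0.881). Camera also called ribosomal (2 of 22 higher, adjusted p = 0.0328) and stress response genes (2 of 33 higher, 0.0173) upward, and small RNA (2 of 8 lower, 0.000976), hnRNP (1 of 24 higher and 1 lower, 0.00528), splicing regulator (2 of 29 lower, 0.0173) and interferon genes (1 of 34 higher and 1 lower, 0.0224) downward. Their adjusted p with an estimated correlation were from 0.346 to 0.597. Adjusted over the list alone, 4 ribosomal and 2 stress response genes were higher, 2 small RNA genes lower, and 1 hnRNP, 1 splicing regulator and 1 interferon gene higher with 1, 4 and 3 lower. Lost were the ribosomal call without untreated array 1 or 2 or non-silencing shRNA array 2 or 3 (adjusted p from 0.0667 to 0.113), the hnRNP and splicing regulator calls without non-silencing shRNA array 2 or 3 (from 0.0542 to 0.115), the interferon call without non-silencing shRNA array 1 (0.0755), and the G2 and M phase and lysosomal calls without untreated array 3 (0.0683 and 0.106). Fry called 8 lists, and the other 17 were not called by camera (adjusted p from 0.114 to 0.986). Limma called 616 clusters, 468 higher and 148 lower, but 289 and 278 after quantile normalization. The count was 159 and 163 without untreated arrays 1 and 2, and 262 and 180 without non-silencing shRNA arrays 2 and 3.

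The knockdown methods were compared by the difference between their effects. The Qki change after siRNA differed from that in the shRNA line by -1.19 ± 0.32, each taken against its own control (adjusted p = 0.0432). Qki itself lay at 9.89 after siRNA and 10.71 in the line, with controls at 11.33 and 10.97. Zdbf2 rose in the line and lay at 0.20 after siRNA, a difference of -3.93 ± 0.20, and Il33, Calcr and Brinp1 had differences of -4.82, -5.43 and -4.29. Hapln1 and Pnlip changed by -0.54 and -0.60 after siRNA, with differences of 4.76 ± 0.57 and 4.64 ± 0.51. H2ac21, a histone gene, and Cytl1, a secreted cytokine-like protein, had differences of 5.05 ± 1.20 and 4.44 ± 0.98. Limma called 890 clusters, 647 positive and 243 negative, or 485 and 480 after quantile normalization. The count lay between 518 and 582 without non-silencing siRNA array 1 or 3, QKI siRNA array 2, non-silencing shRNA array 3 or QKI shRNA array 2.

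The mean of both QKI effects was tested as well, which can pass through 1 method alone and does not show a change common to both. Qki changed by -0.85 ± 0.16 on average (adjusted p = 0.00483) and Mbp by -3.54 ± 0.49 (adjusted p = 0.000639), while the difference for Mbp did not pass (1.40 ± 0.99, adjusted p = 0.582). Limma called 1046 clusters, 339 higher and 707 lower, or 525 and 605 after quantile normalization. The count was 1694 without the array labelled QKI shRNA 3, and 598 to 678 without QKI shRNA array 1 or 2, QKI siRNA array 2, non-silencing siRNA array 2 or 3 or non-silencing shRNA array 3. Across clusters, which are not independent replicates, the effects of QKI siRNA and QKI shRNA correlated at r = 0.144 (rho = 0.047), inside the range of -0.551 to 0.604 from resampled arrays without effects, which does not keep the pairing of these groups by number. Of the 1943 clusters called in the line 1070, or 55.1%, moved the same way after siRNA, where resampled arrays gave 35.2% to 65.1%.

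QKI siRNA and hnRNP A1 siRNA were compared directly, since both regulate splicing. Qki was at -1.16 ± 0.22 (adjusted p = 0.467), Hnrnpa1 at 0.37 ± 0.19 (adjusted p = 1) and Mbp at -1.91 ± 0.70 (adjusted p = 1). Limma called 0 clusters, with 603 at an unadjusted p under 0.05, and 1 without hnRNP A1 siRNA array 3. The effects correlated at r = 0.744 (rho = 0.651) across clusters. Both were taken against the same 3 controls, and simulated unchanged groups with a shared control gave 0.48 on average, from -0.106 to 0.827. The covariance was 0.0624 beside a simulated 0.0285, a difference of 0.0338 that lies inside the simulated spread, and the correlation was 0.166 with untreated cells as the control of hnRNP A1. The draws do not keep the replicate numbers, which are taken to pair QKI and hnRNP A1 siRNA arrays. Such pairing can raise the correlation, so the excess is not shown to come from the knockdowns. With 1 set of 3 controls their part cannot be separated.

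Exon usage was compared because both proteins act on splicing. In the QKI shRNA line, Snd1, a nuclease of RNA silencing, Mga, a transcription factor, and Adgrb1, an adhesion receptor, had lead probe sets at -2.82, -2.68 and -3.25 relative to the rest of the gene (diffSplice adjusted p = 7.64e-13, 8.47e-11 and 1.34e-10). Their lower values, 4.11, 3.06 and 4.55 in the QKI line, lay near or below the array medians of 4.41 to 4.55 at the exon level, so the sizes are uncertain. For Mga the probe set lay at 3.06 against 4.92, and the relative value also holds a rise of the gene by 0.81. For Adgrb1 it lay at 4.55 against 9.79 while the gene itself changed by -1.99, so the probe set fell further in the direction of its gene. With untreated cells as the control Snd1 was at 0.20. For Pcdh10 and S100b the values of 3.85 and 5.50 reflect lead probe sets that did not follow the fall of the gene, at 6.72 against 7.02 and 5.84 against 5.40. Of 19 listed splicing targets tested, Fn1 at 1.60 (adjusted p = 0.0195, splicing index 0.0357) was called, with its lead probe set at 6.32 against 3.68, the latter also below these medians. Mbp at 3.72 was called too (adjusted p = 0.00513, splicing index 0.013), but its lead probe set lay at 3.46 against 3.43, unchanged while the gene fell, so a change of exon usage is not shown. Qki probe sets were not called (adjusted p = 0.211, and 0.0866 after QKI siRNA). DiffSplice called 475 of 10080 genes, against 311 of 9817 with the splicing index, 196 of them shared. With untreated cells as the control it called 68 genes, of which 39 were among the 475. The count was 285 without non-silencing shRNA array 3 and 242 and 203 without QKI shRNA arrays 1 and 2.

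After QKI siRNA the lowest p in exon usage were those of Ntrk2, a neurotrophin receptor, with a lead probe set at 2.84, Krba1 at 3.81, Dync2i1, a dynein subunit, at -3.12, Gpm6b, a proteolipid, at -1.74 and Neb, nebulin, at -2.36. After hnRNP A1 siRNA they were those of Krba1 at 3.59, Coro7, a coronin, at 2.85, Dync2i1 at -3.25, Csrnp3 at -3.07 and Spata20 at -2.35. The lower group lay at 4.06 for Krba1, 3.68 and 3.39 for Dync2i1, 3.03 for Neb, 3.42 for Coro7 and 4.20 for Csrnp3, below the same medians, so these sizes, relative to the rest of the gene, are uncertain as well. DiffSplice called 141 and 32 genes, while the splicing index called 0 in both and in simulated data diffSplice called 135 and 141 unchanged genes. The 141 exceed the 32 called after hnRNP A1 siRNA, so the simulated noise does not match the real one there. QKI siRNA shared 17 called genes with QKI shRNA, where independent lists would share 6.64, and 17 with hnRNP A1 siRNA, where they would share 0.448. Both chance counts leave out that called genes had more probe sets (medians of 13, 12 and 14 for QKI siRNA, QKI shRNA and hnRNP A1 siRNA, against 9) and that the arrays pair by number, and the second also leaves out the shared controls. Without single arrays the first count was 84 (non-silencing siRNA 1), 373, 77 and 72 (QKI siRNA 1, 2 and 3), and the second 19 and 80 (non-silencing siRNA 1 and 2) and 14 (hnRNP A1 siRNA 1).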

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

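Tests chosen after the results were seen are those of the Qki level, of the control line, of separately selected lines, of swapped or wrong labels, of dim probe sets, of the spread of lead probe sets and the use of the splicing index as a test of noise. The rule for outliers covers groups of 4 to 10 arrays, so it was not applied to these groups of 3.

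The changes of QKI siRNA and of the QKI shRNA line, each against its own control, differed at 890 clusters, by limma's test of the difference. That contrast does not separate knockdown from differences between the 2 lines. Among named genes the siRNA effect lay above the shRNA effect by 5.05 log2 units for H2ac21, 4.76 for Hapln1, 4.64 for Pnlip, 4.44 for Cytl1, 4.10 for Cav1, 4.09 for Tril, 3.83 for Sdf2l1, 3.70 for Pcdh10, 3.32 for Jag1, 3.29 for Gpr37l1, 2.70 for Tm7sf2 and 2.39 for S100b. It was 1.89 for Cnp, 1.87 for Olig1, 1.83 for Ifi27, 1.72 for Sox5, 1.64 for Npc2, 1.58 for Lamp2, 1.52 for Pmvk, 1.42 for Fdft1, 1.15 for Ndufv2, 1.08 for Ctsd and 1.04 for Atp5f1c. The differences were -0.84 for Fn1, -1.05 for Bst2, -1.19 for Qki, -1.78 for Mki67, -1.88 for Cenpf, -1.89 for Lef1, -1.97 for Psmb8, -3.30 for Emp3, -3.93 for Zdbf2, -4.29 for Brinp1, -4.82 for Il33 and -5.43 for Calcr. Of 100 drawn splits 2 gave as many calls, the real one included, for the difference (890, highest other 1095) and for the mean (1046, highest other 1095). In the split with 1095 the shRNA groups were left whole and the siRNA arrays mixed, so these counts follow the shRNA effect, and the splits do not test the part of siRNA in them.

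Many clusters were called between the shRNA lines although Qki mRNA differed little between them (10.71 and 10.97, beside 11.44 in untreated cells), while QKI siRNA with a larger Qki change gave 0. With untreated cells as the control, or without QKI siRNA 3 and hnRNP A1 siRNA 3, QKI siRNA also gave calls, though fewer than between the lines, as listed below. If the present Qki mRNA level set the changes between the lines alike with either method, they would be at least as large after siRNA. But their median siRNA change in the called direction was 0.0392, inside the range of -0.0849 to 0.0904 from resampled arrays and far below the 0.921 between the lines. The control line's own distance from untreated cells cannot be told apart as the cause. Its median was -0.522 in the called direction, but clusters and direction were called with these same control arrays, which pushes it that way. In clusters called without 1 QKI shRNA array, the omitted array lay from untreated cells in the called direction by 0.402 and 0.447 for arrays 1 and 2, above resampled upper bounds of 0.114 and 0.111, but by 0.149 for array 3, under its bound of 0.217. No control-line array was omitted in this way. Of the 1943, 318 were called against untreated cells. Differences between separately selected lines, without a role of QKI, may account for the calls: 55.1% moved the same way after siRNA, inside a resampled range that does not keep the pairing of arrays by number, so this cannot be told apart from an effect of lasting knockdown. QKI protein and the time since knockdown were not measured here and stay open.

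Untreated array 3 and QKI shRNA array 3 stood apart from their groups in opposite ways, with deviations correlated at -0.507. The tables argue against a plain swap of their labels: over 118 clusters that set QKI shRNA 1 and 2 apart from 14 arrays of other groups, untreated 3 lay nearer to the QKI line in 18.6% (at most 22.6% with any array that set them left out), and in 38.7% of 155 clusters that separate both groups on the other arrays. A wrong label or mixed material of QKI shRNA 3 alone stays open. Of the 155 it lay nearer to the untreated arrays in 58.7%, and of the 118 nearer to other groups in 58.5%, while Zdbf2 at 7.52, Il33 at 7.95, Hapln1 at 3.44 and Pcdh10 at 3.56 kept the side of its label (3.71, 6.27, 9.43 and 7.02 on untreated 3). Both sets were chosen by the values of QKI shRNA 1 and 2 without either array 3. That choice by itself draws QKI shRNA 3 toward the other groups, and in the 118 it can also lower the share of untreated 3. No other array was omitted as a baseline, so the shares alone do not show a wrong label or mixing. Cell cycle state as the whole cause cannot be told apart: the correlation was -0.267 with the G2 and M phase list mean as a covariate, close to the bound of -0.25 set beforehand, and the need to clear that bound by the spread over omitted arrays (-0.343 to -0.0757) was added after the value was seen. The tables argue against a different spread of values, as the correlation was -0.524 after quantile normalization.

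The exon usage calls after siRNA may come from unequal noise of probe sets within a gene, since a test with a spread for each probe set called 0 genes after QKI siRNA and 0 after hnRNP A1 siRNA, and lead probe sets of called genes had a median spread 1.52 and 1.65 times that of their gene, beside 1.07 in genes not called. The changes stayed while standard errors widened for Ntrk2 (2.84 ± 0.33, then 2.73 ± 0.55), Dync2i1 (-3.12 ± 0.45, then -3.14 ± 0.71) and Neb (-2.36 ± 0.36, then -2.33 ± 0.57) after QKI siRNA. Standard errors hardly widened for Krba1 (3.81 ± 0.46, then 3.68 ± 0.52, splicing index adjusted p = 0.0577) and Gpm6b (-1.74 ± 0.26, then -1.45 ± 0.27, splicing index adjusted p = 0.124), where noise is not shown. In the QKI shRNA line that test called 311 genes, which argues against noise as the whole cause there. Dim probe sets that cannot follow a gene cannot be told apart as a cause. Of 271 called genes changed by 0.5 or more, the lead probe set itself lagged in 130, or 48.0%. In the others, dim probe sets in the rest of the gene could leave a responsive one as the lead, which this count does not see. Real exon usage, dim probe sets and differences between the lines stay open.

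For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. Real and highest other counts of clusters were 0 and 1 for QKI siRNA (10 splits as large), 1943 and 32 for QKI shRNA (1 split), 1 and 4 for hnRNP A1 siRNA (3 splits), 15 and 2 for non-silencing siRNA (1 split), 616 and 6 for non-silencing shRNA (1 split) and 0 and 2 for QKI siRNA against hnRNP A1 siRNA (10 splits). Among the 4 splits that part all pairs of the shRNA lines, the highest other count was 0. In exon usage they were 141 and 185 (2 splits) for QKI siRNA, 475 and 38 (1 split) for QKI shRNA and 32 and 85 (3 splits) for hnRNP A1 siRNA. For lists they were 9 and 11 (4 splits), 8 and 11 (6 splits), 8 and 11 (2 splits), 10 and 11 (2 splits) and 10 and 12 (3 splits), in the order QKI siRNA, QKI shRNA, hnRNP A1 siRNA, non-silencing siRNA and non-silencing shRNA.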

How the results depend on the processing

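Settings chosen after seeing the data are those without 2 arrays, with the G2 and M phase covariate and with the block within 2 groups. The cause of the shifts below was not tested, apart from fewer arrays or features where these are named. Counts for QKI siRNA, QKI shRNA, hnRNP A1 siRNA, non-silencing siRNA, non-silencing shRNA, the difference, QKI siRNA against hnRNP A1 siRNA and the mean ranged over single omitted arrays from 0 to 2, 1316 to 2203, 1 to 26, 2 to 51, 159 to 897, 518 to 1050, 0 to 1 and 598 to 1694. Lists ranged from 5 to 12, 6 to 11, 6 to 12, 8 to 14 and 7 to 11 (QKI siRNA, QKI shRNA, hnRNP A1, both controls), and exon usage from 72 to 373, 203 to 590 and 14 to 80. Qki ranged from -1.54 to -1.33 (QKI siRNA), -0.47 to -0.07 (QKI shRNA) and -0.38 to -0.21 (hnRNP A1 siRNA), Hnrnpa1 from -0.44 to -0.17, 0.06 to 0.33 and -0.76 to -0.63, and the correlations from 0.0638 to 0.265 and 0.557 to 0.808. With only the arrays compared, counts were 2 (QKI siRNA), 1275 (QKI shRNA), 0 (hnRNP A1), 120 (non-silencing siRNA) and 241 (non-silencing shRNA). With untreated cells as the control they were 87, 385 and 56 for the knockdowns, and with both controls 28 for QKI siRNA and 24 for hnRNP A1. Qki after siRNA was called at -1.55 and -1.50 there, and lay at -1.12 by exon-level means. Without untreated 3 and QKI shRNA 3, counts were 25, 3 (hnRNP A1), 197 and 1363 (controls), 2 and 2031 (mean), with Qki called at -1.44. Without QKI siRNA 3 and hnRNP A1 siRNA 3 they were 183, 111, 149 (non-silencing siRNA) and 1, with Qki called at -1.33. With the covariate they were 39, 1400 (controls) and 1. Centring gave 4, 158, 360 (difference) and 639 (mean), quantile normalization 2 (hnRNP A1) and 25, no moderation 2, 6 and 383, trend with robust 6, and a 1.5-fold minimum 656 (mean). The replicate block gave 3 (hnRNP A1) and 57 (non-silencing siRNA), and 212 in exon usage after QKI siRNA, and moved no other count by over 1.5 times. Lists fell to 0 with an estimated correlation in all comparisons and with fry in QKI siRNA, hnRNP A1 and non-silencing siRNA. Exon usage gave 351, 761 and 124 without a filter, 84 and 16 (both siRNAs) above the median, 0, 311 and 0 with the splicing index, 134 (QKI shRNA) without changed genes and 392, 68 and 79 against untreated cells. Without the arrays named above it was 226 and 51, then 61 (hnRNP A1). The correlation with hnRNP A1 was 0.166 with its untreated control. Reversed with untreated cells were Mki67 (-0.42), Pmvk (0.29), Hnrnpa1 (-0.11) and Snd1 exon usage (0.20) in QKI shRNA. Among single named genes 1095 values kept their direction and call, 81 lost the call and 3 gained it, besides the reversed ones, and 514 and 98 kept and lost it over omitted arrays. Without detection calls, how far background limits dim genes is not known.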

Other observations

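The test of this part was chosen after the results were seen. Calcr, Zdbf2 and Slc38a4, among the genes that rose most in the QKI shRNA line, are imprinted in mouse, so imprinted genes might differ between the lines more often than others. Of 47 measured genes on a list of imprinted genes written from general knowledge, 8 were called, 4 higher and 4 lower: Osbpl5 also rose, by 0.65, and Mkrn3, Cd81, Nnat and Dlx5 changed by -0.80, -1.14, -1.77 and -2.89. The share of 17.0% was not shown to differ from the 13.4% of other genes (Fisher's exact test, two-sided p = 0.517), and 5 of 44 were called without the 3 genes that raised the question. A larger share of called genes was thus not shown. The test counts calls of any size in either direction, so it does not address the largest rises, and 47 genes allow only a coarse comparison.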
